A study of Mus musculus with 6 samples.

How the data were processed

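The data are 6 exon array profiles of mouse neural stem cells, 3 nucleofected with a miR-128 mimic and 3 with miR-Control, which the labels call biological replicates. The deposited values are log2 expression values. They were made with RMA and the affy package, per the submitters' processing notes, which give no versions. RMA corrects background, equalises the arrays' distributions and summarises a probe group as 1 log2 value, and its fold changes tend to be smaller than true ratios. Median and interquartile range differed between the deposited columns. The rows are RefSeq transcript accessions, so the table holds transcripts and not exons, and the source of the probe grouping and the genome build of its design are not given in the sources used here. No detection p was used, and signal over background is therefore unknown for each row. The number of arrays limits the precision of every value.

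Row names were matched, without version numbers, to the RefSeq gene table of assembly GRCm38.p6, used for names only. Of 32025 rows 25343 were named, for 20263 genes. Among rows of curated accessions 25289 of 25898 had a name, and among rows of predicted accessions 54 of 6127 did. The 6682 unnamed rows were tested but are not named in the text. Identical values were found in 3058 rows that repeat an earlier row, since transcripts of a gene can share their probes. Of 418 genes in the fixed lists 403 had a row.

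Groups and replicate numbers were taken from the sample titles. The test, its samples, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited values of all 6 arrays, unpaired, two-sided and with no filter on low values. Adjustment was by Benjamini-Hochberg over all 32025 rows, with a threshold of 0.05. The prior had 4.74 degrees of freedom. Fold changes are miR-128 over miR-Control, and ± values are SDs over 3 arrays.

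The lists numbered 22, and 21 of them had at least 5 measured genes and were tested: NMD and exon junction complex factors, known NMD substrates, splicing factors with NMD-coupled exons, genes reported elsewhere as miR-128 targets, small RNA machinery, ATF4 and amino acid response, endoplasmic reticulum chaperones, neural stem cells and radial glia, neurons, astrocytes, oligodendrocyte lineage, microglia, vascular and mesenchymal cells, S phase, G2 and mitosis, interferon response, sterol synthesis, p53 response, Polycomb complexes, immediate early genes and ribosomal proteins. The list of miR-128 host genes was only described. Some genes are in more than 1 list. Each gene was represented by its row of highest mean over all arrays. limma's camera with a preset inter-gene correlation of 0.01 compared each list with all other named genes, adjusted over the 21 lists, with camera at an estimated correlation and fry beside it. A list's percentile was also taken among 10000 random lists of the same size matched on mean level in 50 bins.

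Named genes are those among rows with 1 symbol that passed, and, since none did, the 5 rows a side of smallest p, the 2 members of smallest p of each list, and Upf1, Casc3, Bmi1, Atf4, Gas5, R3hdm1 and Arpp21 whatever their values. Some genes that the rule names are not reported here.

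A test of exons within genes was planned for exon-level rows and was not made, because the rows are transcripts. In its place, chosen after seeing the data, the distinct rows of each gene were compared. limma's diffSplice was run at first and gave few small p-values. It treats a gene's rows as independent, while here they vary together. The reported version tests each row minus the mean of its gene's rows on the same array, with Simes p-values per gene. Both versions made no call. A planned test of miR-128 seed matches in 3' UTRs was not run, since no transcript sequences were used here, and with it the part of the naming rule that rested on seed sites.

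The procedures were tested on simulated data made from the real rows' means and spreads. With 200 of 32025 rows changed, over 20 simulations, 14.2% were recovered at 1.5-fold, 79.3% at 2-fold and 99.4% at 4-fold, with 5.32% false calls. A list of 24 genes shifted by 0.2 had an unadjusted camera p under 0.05 in 20 of 20 simulations with either correlation. Unshifted lists had such a p in 3.18% with the preset and 0.35% with the estimated correlation. The list calls below use adjusted p, so these shares do not apply to them directly. The simulated rows and genes varied independently, with variances drawn from the fitted prior and the same spread on all arrays. Real members of a pathway do not vary independently, and miR-Control replicate 3 stood apart from the other arrays. The recovery shares therefore do not tell how many changes of a given size the real data would miss. In the transcript test 95.8% of genes with a log2 shift of 1 were recovered, with 3.04% false calls. Its rows too were simulated as independent, while the real rows of a gene vary together.

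Alternatives were a replicate block, leaving out each replicate in turn, quantile normalization, median centring, rows above the median level, eBayes with trend and robust, array weights, 1 row per gene, a fold minimum of 1.5, ordinary statistics, the mean of a gene's rows and camera on ranks. Added after seeing the data were 1 row per set of identical values, array weights in the list tests and the alternatives of the transcript test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.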

Results

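The series measured transcript levels in neural stem cells from CD-1 mouse embryos at stage E14.5, propagated as neurospheres, which are floating colonies of dividing stem and progenitor cells. The cells received by nucleofection, an electrical transfection method, either a mimic of the microRNA miR-128 or a control RNA named miR-Control. Total RNA was taken 72 h later from 3 biological replicates of each group, and each of the 6 RNAs was hybridised to its own exon array. The deposited table held log2 values for 32025 RefSeq transcript rows. The comparison addressed which transcripts differ when miR-128 is introduced.

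The arrays had median log2 values of 7.41, 7.40 and 7.54 in miR-Control replicates 1 to 3 and 7.45, 7.49 and 7.49 in miR-128 replicates 1 to 3. The miR-Control replicate 3 array stood apart from the other 5. Its interquartile range of 2.87 was the lowest of the 6, against 2.98 to 3.22 in the others. It lay at 42.5 on the first principal component, which carried 35.4% of the variance, and the other 5 arrays lay between -18.7 and -0.226. Array number, 3 per group, set the precision: the median standard error of a log2 fold change was 0.13, and the 95% interval of the median row reached 0.29 to each side, or 1.22-fold.

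Over all transcripts no row passed the test, and the rows of smallest p were lower with miR-128 for Pnn, Polr1b, Anp32e, Mtrr and Gpatch4 and higher for Pla2g7, Cdh11 and Ppp2r2b. Pnn, which encodes a nuclear speckle protein of the splicing machinery, had a log2 level of 10.15 ± 0.26 in controls and 8.67 ± 0.18 with miR-128 (SD, n = 3), a log2 fold change of -1.48 (SE 0.15), equal to a 2.79-fold lower level. Polr1b, a core subunit of RNA polymerase I, differed by -1.03 (SE 0.13), Mtrr, methionine synthase reductase, by -1.02 (SE 0.14), Anp32e, a histone chaperone, by -1.01 (SE 0.13) and Gpatch4 by -0.98 (SE 0.14). On the higher side, Pla2g7, a secreted phospholipase, differed by 0.69 (SE 0.10), the adhesion gene Cdh11 by 0.67 (SE 0.10), and the phosphatase subunit Ppp2r2b by 0.68 and 0.66 in its 2 named rows (SE 0.10 for both). In each of these rows all 3 miR-128 arrays lay beyond all 3 controls.

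None of the 32025 rows passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.192, for Pnn. The other rows named above had an adjusted p of 0.201. At an unadjusted p under 0.05 there were 2291 rows, 1294 higher and 997 lower with miR-128, where unchanged rows give 1601 on average. The other 9 splits of the same 6 arrays into 3 and 3 gave 543 to 2530 such rows, 2 of them more than the real split, so this count does not stand out from them. The ordinary, unmoderated statistics of the same model gave 0 rows after adjustment and 2037 at an unadjusted p under 0.05. Groups did not overlap in 3796 rows, or 11.9%, where chance gives 10%. When the test was restricted to rows above the median level, 4 rows passed, among them Pnn, Polr1b and Anp32e, which fell, with adjusted p from 0.0142 to 0.0341. Under limma's array weights 24 rows passed, all with adjusted p from 0.0453 to 0.0486.

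**Figure D1:**
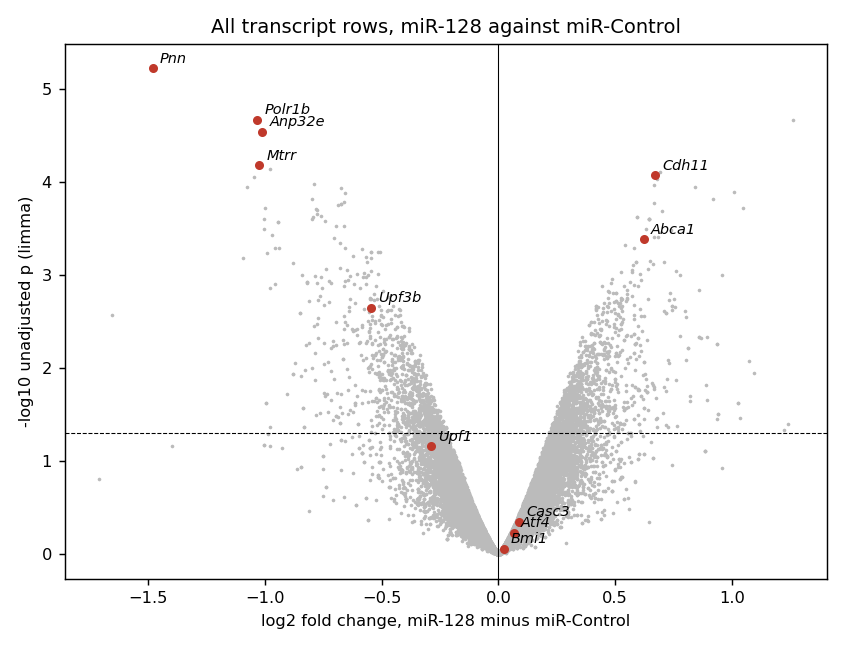
Each point is 1 of the 32025 transcript rows, with the log2 fold change of miR-128 over miR-Control on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis; the dashed line marks an unadjusted p of 0.05. Pnn at -1.48 and Cdh11 at 0.67 lie toward the top on opposite sides, and no row passed after adjustment.

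Of the 21 gene lists tested with limma's camera at its preset correlation, 9 passed, 7 lower and 2 higher with miR-128. With an estimated correlation 0 passed, with a lowest adjusted p of 0.467, and 1, the p53 list, had an unadjusted p under 0.05. By fry, which tests whether a list's genes move one way on balance, 0 passed and 3 had an unadjusted p under 0.05, namely the astrocyte, sterol and p53 lists.

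Genes of nonsense-mediated decay (NMD), the pathway that degrades transcripts with premature stop codons, and of the exon junction complex that marks spliced transcripts were slightly lower with miR-128. Of the 21 measured members 12 were lower and 9 higher, with a mean log2 fold change of -0.10. The 2 members of lowest p were Upf3b at -0.55 (SE 0.13, adjusted p = 0.390) and Upf3a at -0.44 (SE 0.14, adjusted p = 0.532), both adaptors between the junction complex and the decay machinery. Upf1, the central helicase of the pathway, had 9.60 ± 0.08 in controls and 9.31 ± 0.25 with miR-128 (SD, n = 3), a log2 fold change of -0.29 (95% interval -0.60 to 0.03), with an adjusted p of 0.733, and a further Upf1 row gave the same value of -0.29. Casc3, a core junction component, differed by 0.09 (95% interval -0.16 to 0.34, adjusted p = 0.957). No member passed over all rows, and 1, Upf3b, passed when adjusted over the list alone.

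The NMD and junction factors fell as a list in limma's camera with its preset correlation (adjusted p = 0.0315), and this call was lost with adjusted p = 0.502 with an estimated correlation. The list's array means, relative to the mean of the controls, were 0.04, 0.07 and -0.10 in miR-Control replicates 1 to 3 and -0.09, -0.09 and -0.10 in miR-128 replicates 1 to 3, so miR-Control replicate 3 lay as low as the miR-128 arrays. The adjusted p was 0.177 without miR-Control replicate 1, 0.285 without miR-Control replicate 2, 0.0778 without miR-128 replicate 3 and 0.154 after quantile normalization. Without miR-Control replicate 3 the mean difference from other genes moved from -0.11 to -0.17 (adjusted p = 0.00392).

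Transcripts that are themselves known substrates of NMD did not pass as a list: of 16 measured members 10 were higher and 6 lower, with an adjusted p of 0.769. Their median log2 fold change was 0.04 and camera's direction was up, while their mean lay 0.011 below that of other genes (-0.011), so the measures differ in sign, and the mean difference turned to 0.00103 after quantile normalization. Among them the small nucleolar RNA host transcript Snhg12 was at -0.97 (SE 0.17, adjusted p = 0.244), and it alone passed when adjusted over the list alone. Dusp10, a phosphatase of stress kinases, was at 0.35 (adjusted p = 0.542) and Atf4, a translation-controlled transcription factor of the amino acid response, at 0.07 (95% interval -0.20 to 0.33, adjusted p = 0.979). Gas5 had no row under that name.

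Splicing factors whose own transcripts carry exons coupled to NMD had lower values in 13 of 18 members, with a mean of -0.11. Tra2b was at -0.84 (SE 0.17, adjusted p = 0.340) and Tra2a at -0.51 (SE 0.13, adjusted p = 0.443), 2 related regulators of exon inclusion, and both passed when adjusted over the list alone. The list fell with the preset correlation in camera (adjusted p = 0.0315) but not with adjusted p = 0.641 with an estimated correlation. Its array means were 0.05, 0.10 and -0.16 in the controls and -0.08, 0.01 and -0.25 with miR-128. The adjusted p was 0.220 without miR-Control replicate 1, 0.444 without miR-Control replicate 2, 0.550 without miR-128 replicate 3 and 0.116 after quantile normalization. The mean difference from other genes, -0.12 with all arrays, was -0.06 without miR-Control replicate 2, -0.04 without miR-128 replicate 3 and -0.20 without miR-Control replicate 3.

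**Figure D2:**
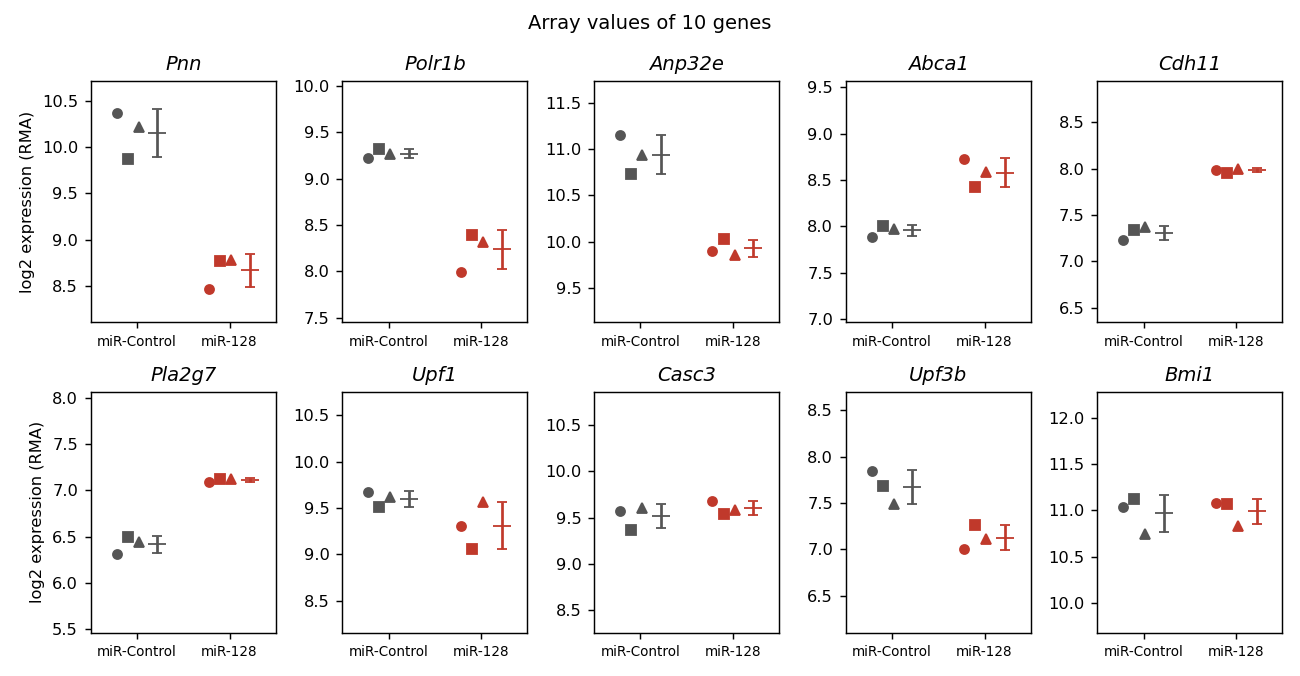
Log2 level of 10 genes on each array, with 1 point per replicate and the mean ± SD of 3 arrays per group. Pnn, Polr1b, Anp32e and Upf3b lie lower in all 3 miR-128 arrays than in all 3 controls, Abca1, Cdh11 and Pla2g7 lie higher, and the groups overlap for Upf1, Casc3 and Bmi1.

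Genes reported elsewhere as targets of miR-128 did not fall as a list. Of 22 measured members 16 were higher, with a mean log2 fold change of 0.10, and the list did not pass (adjusted p = 0.0682). It passed when miR-Control replicate 1 (adjusted p = 0.0316), miR-Control replicate 2 (0.0322) or miR-128 replicate 2 (0.0288) was left out, each time higher. Without miR-Control replicate 3 its mean difference from other genes went from 0.09 to 0.04 (adjusted p = 0.789), and without miR-128 replicate 1 to 0.05 (adjusted p = 0.283). Abca1, a cholesterol exporter, was at 0.62 (SE 0.11, adjusted p = 0.247) and Ntrk3, a neurotrophin receptor, at 0.51 (SE 0.12, adjusted p = 0.393), and both passed when adjusted over the list alone. Bmi1, a Polycomb protein of stem cell self-renewal, was at 0.02 (95% interval -0.28 to 0.32, adjusted p = 0.994), and its sign turned when the arrays were centred on their medians.

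The host genes of miR-128 were too few for a list test: R3hdm1 was at 0.21 (adjusted p = 0.852) and Arpp21 at 0.03 (adjusted p = 0.989), with values of -0.15 to 0.03 over its 9 rows. Genes of the small RNA machinery, which load and act with microRNAs, were higher in 10 of 13 members without passing (adjusted p = 0.0995). The list passed, higher, without miR-Control replicate 1 (adjusted p = 0.0269) and without miR-128 replicate 2 (adjusted p = 0.0176), while without miR-Control replicate 3 its mean difference from other genes went from 0.11 to 0.05 (adjusted p = 0.822). Tnrc6b, a silencing scaffold, was at 0.49 (SE 0.11, adjusted p = 0.380) and passed when adjusted over the list alone, and the Argonaute gene Ago4 was at 0.34 (SE 0.12, adjusted p = 0.607). Polycomb genes did not pass, with 14 of 22 higher (adjusted p = 0.769), Phc3 at 0.34 (adjusted p = 0.581) and Pcgf1 at -0.30 (adjusted p = 0.630).

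Cell cycle genes were lower with miR-128 across almost the whole of both lists. All 23 measured genes of S phase and DNA replication had lower values, with a mean log2 fold change of -0.21, and 22 of 24 genes of G2 and mitosis did, with a mean of -0.20. Examples are the DNA polymerase subunit Pola1 at -0.53 (SE 0.13, adjusted p = 0.416), thymidylate synthase Tyms at -0.34 (SE 0.12, adjusted p = 0.581), and the spindle genes Hmmr at -0.51 (SE 0.12, adjusted p = 0.390) and Tpx2 at -0.41 (SE 0.11, adjusted p = 0.456). No single member passed, over all rows or adjusted over the list alone.

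As lists both fell in camera with the preset correlation, S phase with adjusted p = 6.02e-07 and G2 and mitosis with adjusted p = 6.87e-08. With an estimated correlation neither did, with adjusted p = 0.523 for S phase and adjusted p = 0.502 for G2 and mitosis. The array means of the S phase list, relative to the mean of the controls, were 0.10, 0.17 and -0.27 in miR-Control replicates 1 to 3 and -0.29, -0.15 and -0.18 in miR-128 replicates 1 to 3. Those of the G2 and mitosis list were 0.06, 0.15 and -0.20 in the controls and -0.21, -0.10 and -0.30 with miR-128, so that in both lists miR-Control replicate 3 lay within the range of the miR-128 arrays. Without miR-Control replicate 3 the mean difference from other genes went from -0.22 to -0.36 for S phase and from -0.22 to -0.32 for G2 and mitosis, and without miR-Control replicate 2 to -0.13 and -0.14.

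**Figure D3:**
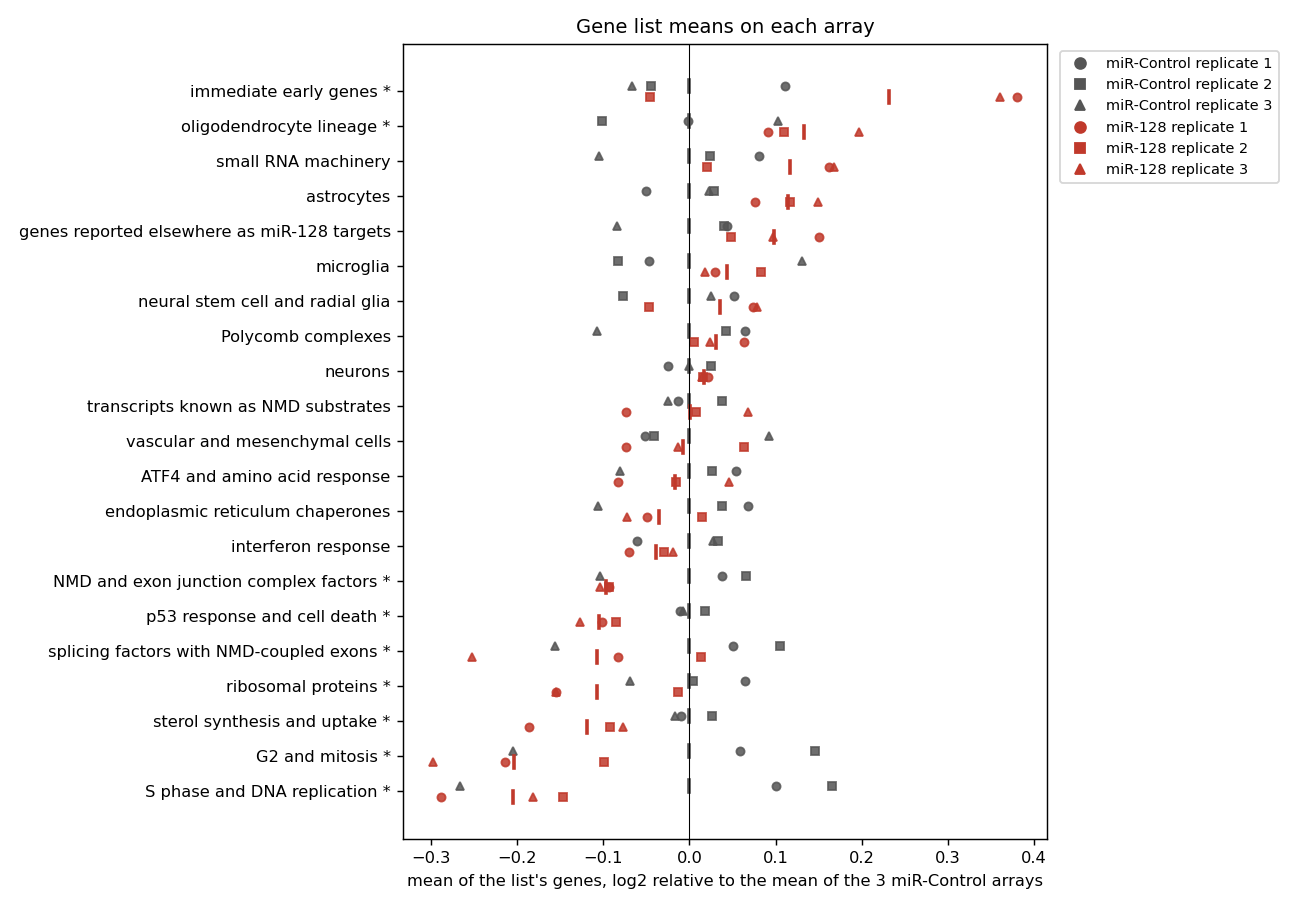
Mean log2 level of the members of 21 gene lists on each array, relative to the mean of the 3 controls, with 1 dot per array, vertical ticks for the group means and an asterisk for an adjusted p under 0.05 in camera with the preset correlation. In the S phase list miR-Control replicate 3 lies at -0.27, within the miR-128 range of -0.29 to -0.15, while in the p53 list all 3 miR-128 arrays lie below all 3 controls.

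Genes of sterol synthesis and uptake were lower in 17 of 23 members, with a mean of -0.12, among them Hsd17b7 at -0.69 (SE 0.17, adjusted p = 0.415) and Sc5d at -0.53 (SE 0.13, adjusted p = 0.415), both enzymes of late cholesterol synthesis that passed when adjusted over the list alone. Genes of the p53 response and cell death were lower in 16 of 19 members, with a mean of -0.10, including the cell cycle inhibitor Cdkn1a at -0.25 (SE 0.10, adjusted p = 0.667), with -0.14 (adjusted p = 0.931) in a further row whose groups overlap, and the death receptor Tnfrsf10b at -0.32 (SE 0.14, adjusted p = 0.695). In these 2 lists all 3 miR-128 arrays lay below all 3 controls. The sterol means were -0.01, 0.03 and -0.02 in the controls and -0.19, -0.09 and -0.08 with miR-128, and the p53 means were -0.01, 0.02 and -0.01 in the controls and -0.10, -0.09 and -0.13 with miR-128. An exact two-sided permutation p of 0.1 for each is the smallest that 3 arrays against 3 allow, and chance gives it in 10% of lists. The miR-128 target and astrocyte lists, which did not pass in camera, also had 0.1. Among the other lists that passed, the permutation p was 0.3 for S phase, 0.2 for G2 and mitosis and 0.4 for NMD and junction factors. It was 0.4 for splicing factors, 0.3 for immediate early genes, 0.2 for ribosomal proteins and 0.2 for the oligodendrocyte lineage.

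In camera with the preset correlation the sterol list fell with adjusted p = 0.00307 and the p53 list with adjusted p = 0.00355. Those calls were lost with adjusted p = 0.502 with an estimated correlation for sterol genes and adjusted p = 0.467 with an estimated correlation for p53 genes, whose unadjusted p was 0.0222. Quantile normalization of the table gave an adjusted p of 0.0546 for the sterol list, and leaving out miR-128 replicate 3 gave 0.0531 for the p53 list.

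Immediate early genes, transcribed within minutes of a stimulus, were higher in 13 of 14 members, with a mean of 0.23. Nr4a1, a nuclear receptor, was at 0.57 (SE 0.19, adjusted p = 0.570) and Egr2, a zinc finger factor, at 0.48 (SE 0.13, adjusted p = 0.461). The list rose with the preset correlation (adjusted p = 0.00222), not with adjusted p = 0.543 with an estimated correlation. Its array means were 0.11, -0.04 and -0.07 in the controls and 0.38, -0.05 and 0.36 with miR-128, so miR-128 replicate 2 lay among the controls. The mean difference from other genes, 0.22 with all arrays, was 0.14 without miR-128 replicate 1 and 0.36 without miR-128 replicate 2, and the adjusted p was 0.0680 without miR-Control replicate 3.

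Ribosomal protein genes were lower in 11 of 16 measured members, with a mean of -0.11, including Rpl14 at -0.34 (SE 0.11, adjusted p = 0.568). The list fell with the preset correlation (adjusted p = 0.0113), not with adjusted p = 0.502 with an estimated correlation. Its array means were 0.06, 0.00462 and -0.07 in the controls and -0.15, -0.01 and -0.15 with miR-128. The adjusted p was 0.197 without miR-Control replicate 1, 0.0732 without miR-128 replicate 3 and 0.0938 after quantile normalization.

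Stress and interferon genes did not pass as lists with equal array weights and all 6 arrays. The ATF4 and amino acid response had 17 of 28 members lower (adjusted p = 0.575), with Vldlr, a lipoprotein receptor, at -0.64 (SE 0.15, adjusted p = 0.390) and the tRNA synthetase Eprs at -0.22 (adjusted p = 0.784). Endoplasmic reticulum chaperones had 12 of 18 lower (adjusted p = 0.180), with Canx at -0.38 (adjusted p = 0.461) and Sdf2l1 at -0.38 (adjusted p = 0.505). Without miR-Control replicate 3 the chaperone list passed, lower, with an adjusted p of 0.0223, while without miR-Control replicate 1 its mean difference from other genes went from -0.05 to -0.00906 (adjusted p = 0.840). Under array weights, an alternative chosen after seeing the data, the chaperone list (adjusted p = 0.0434) and the ATF4 list (adjusted p = 0.0468) passed, both lower. The interferon response had 14 of 26 lower (adjusted p = 0.163), with the RNA-sensing kinase Eif2ak2 at -0.50 (SE 0.12, adjusted p = 0.390) and Tap1 at -0.22 (adjusted p = 0.733). Among level-matched random lists the interferon median lay low, at percentile 1.07, against 18.42 for the ATF4 list and 16.86 for the chaperones. Random lists do not carry the joint movement of a pathway's genes.

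Of the cell type lists, the oligodendrocyte lineage was higher with miR-128 in 12 of 15 members, with a mean of 0.13. Cspg4, a progenitor proteoglycan, was at 0.35 (SE 0.14, adjusted p = 0.649). The list rose with the preset correlation (adjusted p = 0.00744), not with adjusted p = 0.502 with an estimated correlation. Its array means were -0.00205, -0.10 and 0.10 in the controls and 0.09, 0.11 and 0.20 with miR-128, so miR-Control replicate 3 lay within the miR-128 range here too. Without miR-Control replicate 2 the mean difference from other genes went from 0.12 to 0.07 (adjusted p = 0.147), and without miR-128 replicate 3 the adjusted p was 0.0537.

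Astrocyte markers were higher in 10 of 13 members, with all 3 miR-128 arrays above all 3 controls, but did not pass (adjusted p = 0.0782). Apoe, a lipid carrier, was at 0.55 (SE 0.12, adjusted p = 0.386) and Slc1a2, a glutamate transporter, at 0.47 (SE 0.13, adjusted p = 0.456), and both passed when adjusted over the list alone. Markers of neural stem cells and radial glia did not pass, with 18 of 25 higher (adjusted p = 0.575). In that list Id3 was at -0.61 (SE 0.14, adjusted p = 0.390) and passed when adjusted over the list alone, and Fabp7 was at -0.30 (adjusted p = 0.641). Neuronal markers were higher in 17 of 29 members (adjusted p = 0.769), with a mean difference from other genes that turned in sign after quantile normalization, and with Gap43 at -0.41 (adjusted p = 0.532).

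Microglial markers were higher in 9 of 10 members (adjusted p = 0.615), with Aif1 at 0.16 (adjusted p = 0.890) and C1qa at 0.14 (adjusted p = 0.926). Vascular and mesenchymal markers had a median of 0.01 with 8 of 14 higher, while their mean was -0.01 and camera's direction was down (adjusted p = 0.736), with Tek at -0.17 (adjusted p = 0.843) and Flt1 at -0.11 (adjusted p = 0.925).

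Transcript rows of the same gene were compared for differences between transcripts, the other question of the series. Among 2969 genes with more than 1 distinct row, holding 7309 rows, none passed in limma for a row that moved apart from its gene's mean, with a lowest adjusted p of 0.366. At an unadjusted p under 0.05 there were 122 genes, where chance gives 148. limma's diffSplice on the same rows also gave 0 genes by its Simes and its F test, with 9 at an unadjusted p under 0.05 by each. The rows of a gene moved almost together between arrays, with a median correlation of their deviations of 0.981. Since transcripts of a gene can share their probes, neither this correlation nor the lack of calls shows that its transcripts behaved alike.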

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

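The comparison of lists under array weights, 1 row per set of identical values and the transcript test with its alternatives were chosen after seeing the data. The count of 0 changed rows in limma held in all alternatives except the restriction to rows above the median level, with 4 rows, where fewer rows were tested and the variance prior was fitted to those rows, and array weights, with 24 rows, which down-weight miR-Control replicate 3 (weight 0.279, against 0.754 to 2.12). Above the median level the unadjusted limma p of Pnn went from 6.01e-06 to 8.84e-07 at the same log2 fold change. The number of rows tested does not enter that p, whereas the prior does. What share of the calls each of these gave was not tested, nor was the cause under array weights. At an unadjusted p under 0.05 the alternatives gave 1285 rows, without miR-128 replicate 1, to 4577, with array weights. Without miR-Control replicate 3 there were 3981 and again 0 after adjustment. The median log2 fold change of all rows lay between -0.01 and 0.05 throughout. The transcript test gave 0 genes in each alternative run. Whether same-numbered replicates shared more than a number cannot be told from their deviations, which correlated by -0.00278, 0.173 and 0.0515 for numbers 1 to 3. The miR-Control replicates 2 and 3 correlated best with their own number, and miR-Control replicate 1 with miR-128 replicate 3 (0.189). The replicate block gave 0 rows, 9 lists and 0 transcript genes, so no count of calls moved. Of 271 list values under alternatives 214 kept their direction and side of the threshold, and of 862 values of named genes 840 did. Several settings, such as the replicate block, leave the value itself as it was, so its direction could not change there. No named gene had passed in the main fit, so these counts are no measure of how firm the results are. The 9 lists that passed became 0 with an estimated correlation, 5 after quantile normalization, 11 under array weights, where the endoplasmic reticulum chaperones (-0.0920) and the ATF4 response (-0.0827) passed in addition, and 4 to 11 when 1 array was left out; for calls lost, the cause was not tested unless a value is given. With an estimated correlation, which leaves the mean difference from other genes as it was, the calls lost were NMD and junction factors -0.109, splicing factors -0.119, oligodendrocyte lineage 0.121, S phase -0.217, G2 and mitosis -0.216, sterol synthesis -0.130, p53 response -0.116, immediate early genes 0.221 and ribosomal proteins -0.119. After quantile normalization they were NMD and junction factors -0.0868, splicing factors -0.0986, sterol synthesis -0.104 and ribosomal proteins -0.0875. Among rows above the median level they were NMD and junction factors -0.0674, splicing factors -0.0571 and ribosomal proteins -0.0796, and with camera on ranks NMD and junction factors -0.109 and splicing factors -0.119. Leaving out 1 array at a time ended the call in some of the 6 fits and not in others for these lists, whose mean differences over all 6 fits ranged as follows: NMD and junction factors -0.167 to -0.0736, splicing factors -0.203 to -0.0382, oligodendrocyte lineage 0.0725 to 0.166, p53 response -0.128 to -0.0966, immediate early genes 0.136 to 0.362 and ribosomal proteins -0.164 to -0.0824. The S phase, G2 and mitosis and sterol lists passed in all 6 such fits. Values that had not passed and turned in sign were, after quantile normalization, NMD substrates 0.00103 and neurons -0.00300, among rows above the median level NMD substrates 0.00426 and neurons -0.0269, with array weights vascular markers 0.00318, Polycomb genes -0.0172 and Bmi1 -0.0110, and with median centring Bmi1 -0.00531. Others turned in sign in some of the fits without 1 array, and over all 6 such fits their ranges were: Arpp21 -0.0394 to 0.101, Atf4 -0.0170 to 0.137, Bmi1 -0.0888 to 0.101, NMD substrates -0.0364 to 0.0160, ATF4 response -0.0755 to 0.00297, neural stem cells -0.0132 to 0.0666, neurons -0.00711 to 0.0201, microglia -0.00766 to 0.0912, vascular markers -0.0527 to 0.0204 and Polycomb genes -0.0411 to 0.0559. Not run were the seed match test with its alternatives, for lack of transcript sequences here, and the microglial and vascular lists among rows above the median level, where under 5 members were left. Signal over background was not known per row, so a low level cannot be told from none.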

Other observations

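The tests of the miR-Control replicate 3 array, of cell make-up, of cycling between cultures and of the number of rows in other splits were chosen after the result was seen, and the ribosome biogenesis list was written after the genes of lowest p were seen. The genes that passed under array weights, 19 in all, were 6 that rose and 13 that fell. Chosen after their values were seen, the ones outside the naming rule include Erbb4, a neuregulin receptor, which rose by 1.21 on the log2 scale, and Kcnj10, a glial potassium channel, by 0.74. Among those that fell were the glucose transporter Slc2a1 at -0.70, the membrane-binding protein Anxa2 at -0.92, Ndufa2, a subunit of respiratory complex I, at -1.18, and the nucleolar gene Wdr46 at -0.90. Adjusted p lay between 0.0453 and 0.0486 for all 24 rows, while without weights no adjusted p of these rows was under 0.192. Another split of the arrays was miR-Control 1, miR-Control 2 and miR-128 3 against the rest. With array weights estimated anew for that split it gave 5199 rows, against 24 in the real split, and 0 without weights. Whether a structure of the samples or the weights themselves gave those calls was not tested. For the 4 rows that passed among rows above the median level, Pnn, Polr1b and Anp32e among them, the other 9 splits gave 0 rows each.

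Genes of ribosome biogenesis were lower with miR-128 in 63 of 69 measured members. The list was written from general knowledge without Polr1b, Wdr46 and Gpatch4, whose low values had prompted it. Its median log2 fold change was -0.21, against 0.02 for the other genes. When adjusted over the list alone Gar1 (-0.66), Heatr1 (-0.56), Utp6 (-0.55) and Rrs1 (-0.49), factors of ribosomal RNA processing and modification named after their values were seen, passed, and none did over all rows.

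The pattern of nucleolar genes among the lowest p-values was tested with that list as a hypothesis of generally lower ribosome biogenesis transcripts with miR-128. The same arrays gave both the pattern and the test, so the test is not independent of what prompted it. The difference of the list's median from that of the other genes was -0.231, beyond the 0.1 set for it in advance, with a camera p of 3.02e-17 at the preset correlation and p = 0.144 with an estimated correlation. The prediction set no limit on that last p, but the test as first run also required it to be under 0.05, which it is not, and this requirement was dropped after the result was seen. The array means were 0.07, 0.15 and -0.21 in miR-Control replicates 1 to 3 and -0.30, -0.13 and -0.22 in miR-128 replicates 1 to 3, so miR-Control replicate 3 lay within the miR-128 range. The S phase list had similar array means, 0.10, 0.17 and -0.27 in the controls and -0.29, -0.15 and -0.18 with miR-128. The ribosome biogenesis and S phase lists therefore cannot be counted as separate observations. The median difference was -0.132 without miR-Control replicate 2 and -0.364 without miR-Control replicate 3. Lower ribosome biogenesis may accompany miR-128 in these cells, but a difference between cultures apart from miR-128 stays open, since 1 control lies in the same range. Whether the culture or the array itself put that control there cannot be told from these values.

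For the lower cell cycle lists, a trend with expression level is argued against, as the median of the G2 and mitosis list lay at percentile 0.01 of 10000 level-matched random lists. The miR-Control replicate 3 array is not the source of the lower values, because it was itself the lowest control in this list, so that leaving it out could only widen the list's difference from the other genes, to -0.324. Cycling that differed between cultures irrespective of miR-128 is a candidate explanation: the list's mean in miR-Control replicate 3, -0.205 relative to the controls' mean, lay within the miR-128 range. That array also had the lowest interquartile range of all, and the effect of a compressed signal on its list mean was not tested. A make-up with fewer cycling cells stays open too. By mean difference, 4 of the 5 marker lists of non-stem cell types lay above the other genes (neurons, astrocytes, oligodendrocyte lineage and microglia). The vascular and mesenchymal list lay -0.0194 from the other genes, with a camera p of 0.631. Among level-matched random lists, the medians of the astrocyte and oligodendrocyte lists lay at percentiles 86.83 and 99.28. Those of the neuron, microglia and vascular lists lay at percentiles 29.2, 32.03 and 20.23. The count of 4 therefore does not hold for medians at matched level. An effect of miR-128 on proliferation, the biological explanation the design gives, stays among the open ones.

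The miR-Control replicate 3 array stood apart, and a compressed signal range was tested as its technical explanation. Its regression slope on the mean of the other arrays was 0.950, the lowest of the 6, against 0.985 to 1.03. Its SD of differences from the other arrays was 0.294, and after that straight line was removed its residual SD was 0.275. The other arrays had residual SDs of 0.180 to 0.231, so the fall into their range that was predicted for compression did not occur. Its value was 1.19 times the highest of them, just within the limit of 1.2 written for the test against compression. By those limits compression alone cannot be told apart from a difference in the sample. No biological explanation was tested, since the design names none for a single control.

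In 10 splits of the 6 arrays into 3 and 3, a share under 0.05 cannot be reached. The 9 lists past the threshold in the real split were matched in 1 other, so that 2 of the 10 splits gave 9 or more, the highest of the other splits giving 9. For rows, the real split gave 0 and the highest other 2, so that 10 of 10 splits had as many or more, and for genes with transcripts moving apart it gave 0 and the highest other 0, again 10 of 10. A real count of 0 makes 10 of 10 certain, so the row and transcript comparisons carry no information.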
